A study of Mus musculus with 6 samples.

How the data were processed

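Liver RNA of 6 male C57BL/6J mice was measured on 6 oligonucleotide arrays, 1 array per mouse. The labels place 3 mice in a control group whose feed held 4% cellulose and 3 in a garlic group whose feed held 4% freeze-dried raw garlic powder, each for 15 weeks from an age of 8 weeks. The labels call the mice of a group biological replicates, so the spread within a group is that between separate animals. They name no batch, and no array was left out. The array is a 1-colour Affymetrix mouse array hybridised with biotin-labelled RNA.

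The deposited values are probe-set signal intensities on a linear scale, made by the authors with MAS5, per the submitters' processing notes. MAS5 subtracts a local background and the signal of mismatch probes and then scales every array to a common mean. The version, settings and detection calls of MAS5 are not given in the sources used here. In the deposited table the mean signal after trimming 2% of probe sets at each end was 500.004 on all 6 arrays, so the scaling had been applied, and no further normalization between arrays was added. This scaling fixes the mean of each array, so a change shared by most transcripts would not be seen. Signals near background scatter widely on a log scale, and an offset and a filter were used to limit this. The number of arrays limits the precision of every value.

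The table held 45101 probe sets, of which 64 were control probe sets and were left out of all tests between the diets. Of the other 45037, the 2016 platform annotation gave exactly 1 gene symbol to 34945, several to 932 and none to 9160. No symbol needed updating. Probe sets with several symbols were not named. A gene was represented by the probe set with the highest mean log2 signal, which gave 18193 genes. A gene was tested where that mean was at or above the median of all 45037 probe sets, which left 11292 genes. Values were taken as log2(signal + 16), so a fold change understates the difference of a dim gene. No genome was used, and positions of genes are not given here.

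Garlic and control arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend of variance on signal), two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. All adjusted p-values of genes come from this fit, and ± after a fold change is its standard error. An exact permutation test of 3 arrays against 3 cannot give a two-sided p below 0.10, so none is reported. Means ± SD are of deposited signals.

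The text names, per direction, up to 15 genes with the largest fold change among those that passed with all arrays of 1 diet beyond all of the other. Where fewer than 10 passed in a direction, the genes with the smallest unadjusted p among those with non-overlapping groups were added until 10 were named, leaving out clone names and gene models. From a gene list, up to 4 members with the smallest p are named, or up to 8 where they passed adjustment over the list alone. That adjustment takes no account of the number of lists, so some such passes can arise by chance. A further set was named whatever the values, and genes of that set that the report does not name were not analysed here.

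From textbook knowledge, 32 gene lists and 12 lists of cell type markers were written. Of their 909 gene entries, 801 matched a gene on the array. The 38 lists with at least 5 tested members were tested with limma's camera with a preset correlation between genes of 0.01, two-sided, adjusted over those lists. Each list was also tested with an estimated correlation and with fry, which asks whether the genes of a list move on balance one way without comparing them with other genes. The groups, the tests, the filter, the lists, the rule for named genes and the alternative settings were fixed before the data were examined.

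The alternatives were offsets of 1 and 64, quantile normalization, centring each array on its median, no filter, a filter at the 70th percentile, the mean of all probe sets of a gene, every probe set on its own, eBayes without a trend or with robust variances, array weights, treat with a fold of 1.2 as the null, the replicate number as a block, and leaving out each array in turn. The fit was tested on simulated data with the spread of these arrays, with 200 of the 11292 genes changed in each of 10 runs. It recovered 30.1% of genes changed by 0.5 on the log2 scale, 78.2% of those changed by 1 and 97.0% of those changed by 2, and 7.14% of the calls were false. A simulated shift of 0.4 of the heat shock protein list was called in 10 of 10 runs with the preset correlation and in 9 with an estimated one. Genes were drawn independently of each other in these runs, while the estimated correlation of that list in the data was 0.34. The runs therefore do not show how either test behaves with correlated genes. Bootstrap intervals over genes used 10000 draws. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.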

Results

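Gene expression was measured in the livers of 6 male mice of the inbred strain C57BL/6J, each on its own array. From 8 weeks of age the mice ate a purified diet based on casein and cornstarch for 15 weeks. Fibre in the form of cellulose made up 4% of the diet of the control mice (n = 3), and garlic, freeze-dried raw and ground to a powder, took its place at 4% in the diet of the garlic mice (n = 3). The median signal of the control arrays was 102, 89.9 and 83.3 in replicates 1, 2 and 3, and that of the garlic arrays was 83.4, 82.7 and 84.1. Pearson's r of log2 signals was taken across the probe sets with a mean log2 signal at or above the median. It lay between 0.9715 and 0.9758 for pairs of control arrays and between 0.9749 and 0.9760 for pairs of garlic arrays. For pairs across the diets it lay between 0.9626 and 0.97503.

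The comparison of the diets asks which liver transcripts differ after prolonged feeding of garlic in place of cellulose. An effect of the garlic and an effect of the missing cellulose cannot be told apart in this design. Signals of heat shock proteins and of genes of endoplasmic reticulum stress and the unfolded protein response were higher in garlic livers. Signals of genes of fatty acid synthesis and of MHC class II antigen presentation were lower. These 4 lists were called with a preset correlation between genes and not with an estimated one, where the adjusted p was 0.427 or more. No gene passed the adjusted threshold by itself. With the preset correlation, splits of the arrays that mix the diets called from 3 to 13 lists, against 12 with the real split. The number of lists called therefore does not set the diets apart from other groupings of the arrays. Hspa1b, which encodes the stress-inducible chaperone Hsp70, had a mean signal of 833 ± 269 (SD, n = 3) in control livers and 11717 ± 8097 (SD, n = 3) in garlic livers, the highest log2 fold change of the genes tested (3.47 ± 0.54, adjusted p = 0.155). Neat1, a nuclear non-coding RNA that scaffolds paraspeckles, had a mean signal of 2709.9 ± 802 in control livers and 922 ± 241 in garlic livers (log2 fold change −1.52 ± 0.24, adjusted p = 0.155). The other Neat1 probe set past the filter differed by −0.56.

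Among 11292 genes tested with limma, 0 were higher and 0 were lower in garlic livers at the adjusted threshold, and the smallest adjusted p was 0.155. At an unadjusted p under 0.05, 530 genes were higher and 667 lower, 1197 in all, where 565 would pass if no gene differed. Without garlic replicate 3 the count of higher genes was 353. In 906 genes all 3 garlic arrays lay above all 3 control arrays and in 963 they lay below, together 16.6% of the genes, where chance gives 10%. Leaving out garlic replicate 1 let 5 genes pass as higher, Hspa1b, Hspb1, Dnajb1, Hsph1 and Dynll1, and 1 as lower, Srsf5. Without control replicate 3, 6 genes passed as higher, among them Tsc22d3, Tat and Igfbp1, and 4 as lower, among them Pnn and Neat1. The counts were 1 and 1 without control replicate 2, and 0 and 1 without garlic replicate 3.

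Besides Hspa1b, the 10 genes with the smallest p among those higher in garlic livers included Hspb1, a small heat shock protein, at 1712 ± 309 in control and 3951 ± 1345 in garlic livers, and Tsc22d3, a transcriptional regulator induced by glucocorticoids, at 2808 ± 1231 and 5923 ± 721. Dynll1, a light chain of dynein, was 1.88-fold higher, H2ax, a histone variant phosphorylated at DNA breaks, 1.66-fold, and Yipf5, a membrane protein of the Golgi, 1.58-fold. The magnesium transporter Slc41a2 was 1.55-fold higher. Manf, a secreted protein induced by stress of the endoplasmic reticulum, and Rnaseh2c, a subunit of an RNase H, were both 1.47-fold higher. Dio1, the deiodinase that makes active thyroid hormone in liver, was 1.43-fold higher. With the mean of all probe sets of a gene in place of the brightest, the log2 fold change of Yipf5 was 0.33 against 0.66, that of Dynll1 0.61 against 0.91 and that of Tsc22d3 0.73 against 1.15. That mean also takes in probe sets below the signal filter. The 10 genes were chosen among those in which all 3 garlic arrays of the brightest probe set lay above all 3 control arrays. None passed (adjusted p from 0.155 to 0.199).

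**Figure D1:**
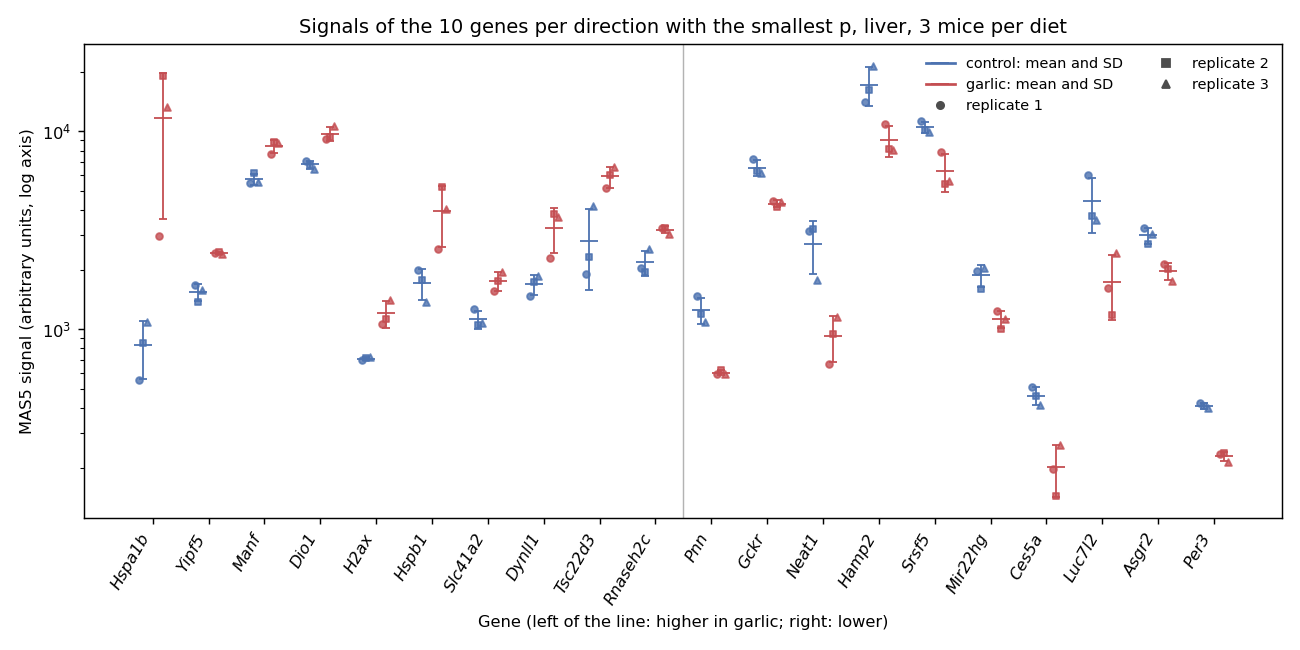
MAS5 signal (arbitrary units, log axis) of the 10 genes per direction with the smallest p, with each array as a point (circle, square and triangle for replicates 1, 2 and 3) and the mean and SD of 3 mice per diet as bars. The 20 genes were chosen among those in which no garlic array overlaps a control array. Hspa1b in garlic livers ranges from 2976 to 18959.

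Among the 10 genes with the smallest p that were lower in garlic livers, Pnn, Luc7l2 and Srsf5 encode proteins of pre-mRNA splicing. Their signals were 2.03-fold lower for Pnn, 2.57-fold for Luc7l2 and 1.68-fold for Srsf5. Mir22hg, the host transcript of a microRNA, was 1.65-fold lower. Hamp2, a relative of the iron hormone hepcidin, had a signal of 17243 ± 3830.3 in control and 9019 ± 1575 in garlic livers, while Hamp, which encodes hepcidin, was at 43198 ± 6658 and 46622 ± 795, and probes of these similar genes can share sequence. Gckr, the regulatory protein of glucokinase, and Asgr2, a subunit of the asialoglycoprotein receptor, were both 1.51-fold lower, and the carboxylesterase Ces5a was 2.26-fold lower. The clock gene Per3 had a signal of 410.5 ± 13.1 in control and 229 ± 12.2 in garlic livers. Again no gene passed (adjusted p from 0.155 to 0.199). In each, all 3 garlic arrays lay below all 3 control arrays, which was a condition for naming these genes. The 2156 probe sets past the filter that carry no gene name moved with these genes: relative to named probe sets of the same brightness they were lower in garlic livers by a log2 difference of −0.13, with all 3 garlic arrays below all 3 control arrays. Further probe sets passed the filter for 10 of the 20 genes, and while none of these 23 probe sets pointed in the opposite direction, many differed by less than the brightest one. The log2 difference was −0.19 and −0.21 in those of Pnn, against −1.02, and from −1.11 to −0.15 in those of Luc7l2, against −1.36. It was 0.13 and 0.20 in those of Yipf5, against 0.66, and 1.19 and 0.39 in those of Tsc22d3, against 1.15. In those of Rnaseh2c it was 0.21 and 0.37, against 0.55. Others lay near the brightest one, with 3.25 and 3.18 in those of Hspa1b, against 3.47. The values were 1.26 for Hspb1, against 1.16, and 0.90 and 0.77 for Dynll1, against 0.91. Those of Per3 ran from −1.92 to −0.35, against −0.80. With the mean of all probe sets of a gene the log2 fold change was −0.47 for Pnn, −0.55 for Luc7l2, −0.45 for Hamp2, against −0.92, and −0.11 for Ces5a, against −1.17.

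Heat shock proteins rose as a list. Of 19 members measured, 18 had a higher signal in garlic livers, with a median log2 fold change of 0.40 (camera adjusted p = 4.38e-12, and adjusted p = 0.427 with an estimated correlation). No member passed over all genes, and 12 passed when adjusted over the list alone, all of them higher. They included Hspa1b, Hspb1 and Dnajb1, an Hsp40 co-chaperone, at 984 ± 162 in control and 2257 ± 928 in garlic livers. Hsp90aa1, a cytosolic Hsp90 and also among them, was at 9851 ± 957 and 13914 ± 2348. Hspa1a, a near-identical copy of Hspa1b whose probe sets cannot be taken as a separate measurement, was at 62.3 ± 50.2 and 674 ± 703. The mean log2 shift of the list was 0.32, 1.07 and 0.81 in garlic replicates 1, 2 and 3. The array of garlic replicate 2 also carried an 18S ribosomal RNA control signal of 22213, against 1942.5 to 4223.5 on the control arrays.

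Genes of endoplasmic reticulum stress and the unfolded protein response rose as well, with 22 of 25 measured members higher in garlic livers and a median log2 fold change of 0.30 (camera adjusted p = 5.16e-09, and adjusted p = 0.427 with an estimated correlation). Adjusted over the list alone 8 members passed, all higher, against 0 over all genes. Among them, Manf went from 5732 ± 373 in control to 8418 ± 626 in garlic livers, Herpud1, part of the machinery that degrades misfolded proteins, from 14587 ± 1849.7 to 22266 ± 4154, the chaperone Dnajb9 from 4609 ± 908 to 7968 ± 2266, and Creld2, a secreted stress protein, from 1624 ± 166 to 2821 ± 809. Proteasome subunits were shifted upward by a small amount, with 19 of 24 higher and a median log2 fold change of 0.05 (camera adjusted p = 0.0209, and adjusted p = 0.891 with an estimated correlation), and Psmb3 was at 5834 ± 277 and 7257 ± 819. That call was lost under quantile normalization, where the adjusted p was 0.435, a stricter filter (0.0620), the mean of all probe sets (0.333), every probe set on its own (0.102), no trend of variance (0.0792), and without control replicate 1 (0.594), control replicate 2 (0.113), garlic replicate 1 (0.0525) or garlic replicate 3 (0.181). With 1 array left out its median ran from 0.013 without control replicate 1 to 0.12 without control replicate 3.

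**Figure D2:**
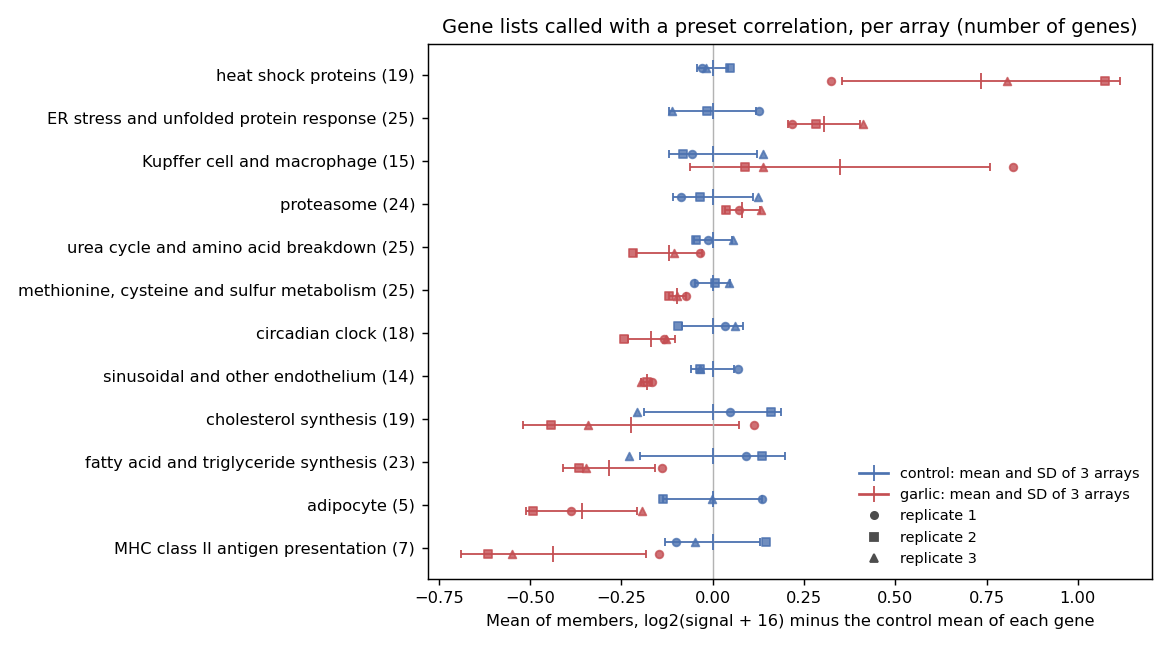
Mean over the members of each of the 12 lists called with a preset correlation, as log2(signal + 16) minus the control mean of each gene, for each array (symbols for replicates 1 to 3) with the mean and SD of the 3 arrays of a diet; the number of genes follows each name. Heat shock proteins reach 1.07 in garlic replicate 2, and Kupffer cell markers reach 0.82 in garlic replicate 1 and lie at 0.09 and 0.14 in the others.

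Fatty acid and triglyceride synthesis genes fell as a list. In garlic livers 21 of 23 members were lower, with a median log2 fold change of −0.24 (camera adjusted p = 4.83e-05, and adjusted p = 0.585 with an estimated correlation), and 0 members passed adjusted over the list alone. The arrays of the diets overlapped, with a mean log2 shift of the list of 0.09, 0.14 and −0.23 in control replicates 1, 2 and 3 and of −0.14, −0.37 and −0.35 in garlic replicates 1, 2 and 3. Acacb, an acetyl-CoA carboxylase, was at 1443 ± 297 in control and 957 ± 128 in garlic livers, Acss2, an acetyl-CoA synthetase, at 6835 ± 1417 and 4289 ± 1711, and Mlxipl, the carbohydrate-responsive activator of lipogenic genes, at 5265 ± 1586 and 3374 ± 479. Fasn, the fatty acid synthase, was at 6322 ± 2292 and 4094 ± 803. Its log2 fold change was −0.57, and it was −0.34 without control replicate 1 and −0.90 without control replicate 3. Lpin1, a phosphatidate phosphatase that is also induced by fasting, went the other way, from 2660.4 ± 347 to 5001 ± 2107. Cholesterol synthesis genes were shifted downward too, with 16 of 19 lower and a median of −0.21 (camera adjusted p = 0.00238, and adjusted p = 0.891 with an estimated correlation). Hmgcs1 was at 9175 ± 1815 and 6897 ± 1189.7, and Idi1, an isomerase of the same pathway, at 2948 ± 466 and 2142 ± 757. The call of the cholesterol list was lost without control replicate 2 (adjusted p = 0.0734) or garlic replicate 2 (adjusted p = 0.198). Its median ran from −0.41 without garlic replicate 1 to −0.13 without garlic replicate 3.

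MHC class II antigen presentation genes fell as a list, with all 7 members lower in garlic livers and a median log2 fold change of −0.49 (camera adjusted p = 0.000515, and adjusted p = 0.551 with an estimated correlation). The mean log2 shift of the list was −0.15 in garlic replicate 1, near the −0.10 of control replicate 1, and −0.61 and −0.55 in garlic replicates 2 and 3, the former being the array with the 18S ribosomal RNA signal of 22213. The 4 members that passed adjusted over the list alone were H2-Ab1 at 1216 ± 162 in control and 771 ± 118 in garlic livers, the invariant chain Cd74 at 3047 ± 556 and 2013 ± 459.9, H2-Eb1 at 1662 ± 237 and 1119 ± 287, and H2-Aa at 3333 ± 565 and 2425 ± 581. Markers of Kupffer cells and macrophages, cells that also carry MHC class II, moved upward instead, with 12 of 15 higher and a median of 0.25 (camera adjusted p = 0.00171, and adjusted p = 0.891 with an estimated correlation). The scavenger receptor Marco was at 174 ± 42.1 and 1007 ± 1011, Lyz2 at 1892 ± 80.7 and 3350.4 ± 1385, and the complement subunit C1qb at 2211 ± 178 and 3025 ± 341, and these 3 passed adjusted over the list alone. The Kupffer shift rested on garlic replicate 1, where Marco reached 2175, and without it the median was 0.010 and the adjusted p 0.264. The log2 fold change without that array was 1.23 against 2.002 for Marco and 0.43 against 0.75 for Lyz2. The Kupffer median was 0.41 without garlic replicate 2. Markers of B and plasma cells had a median of −0.22 and were not called (adjusted p = 0.653).

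Endothelial markers fell slightly, with 11 of 14 lower and a median log2 fold change of −0.14 (camera adjusted p = 0.0209, and adjusted p = 0.427 with an estimated correlation), led by Stab2, a scavenger receptor of sinusoidal endothelium, at 1737 ± 115 in control and 1232 ± 122 in garlic livers. All 5 adipocyte markers measured were lower, with a median of −0.35 (camera adjusted p = 0.0209, and adjusted p = 0.427 with an estimated correlation). Fabp4 was at 806 ± 95.1 and 609.7 ± 101, and hepatocytes also express some of these markers. The endothelial call was lost without control replicate 1 (adjusted p = 0.0636), garlic replicate 1 (0.0557) or garlic replicate 2 (0.0615) and with the mean of all probe sets (0.120). The adipocyte call was lost without control replicate 1 (0.0964) or garlic replicate 2 (0.0680), without the filter (0.0732) and with the mean of all probe sets (0.241).

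Genes of the urea cycle and amino acid breakdown fell as a list, with 20 of 25 lower and a median log2 fold change of −0.11 (camera adjusted p = 0.00212, and adjusted p = 0.840 with an estimated correlation). Adjusted over the list alone 5 members passed as lower, among them the proline dehydrogenase Prodh at 4753 ± 349 in control and 3339.7 ± 362 in garlic livers and the aminotransferases Got1 at 11725 ± 1952 and 7671 ± 1846 and Gpt at 7512 ± 636 and 5719 ± 669. Tat, the tyrosine aminotransferase induced by glucocorticoids, passed in the opposite direction, at 14425 ± 5592 and 24329.6 ± 2442. Genes of methionine, cysteine and sulfur metabolism, which handle the sulfur amino acids, were shifted downward with 17 of 25 lower and a median of −0.13 (camera adjusted p = 0.0209, and adjusted p = 0.580 with an estimated correlation). Cdo1, the cysteine dioxygenase, was at 34327 ± 1152 and 30158 ± 848, and Bhmt, which remethylates homocysteine, at 59075 ± 2976 and 43673 ± 13475. Without garlic replicate 2, where Bhmt read 28326, its log2 fold change was −0.20 against −0.49. The list median without it was −0.045 for amino acid breakdown (−0.17 without garlic replicate 1) and −0.070 for sulfur metabolism. Without control replicate 3 or garlic replicate 2 both calls were lost, with adjusted p of 0.0634 and 0.0680 for amino acid breakdown and 0.195 and 0.0680 for sulfur metabolism, which was also lost with the mean of all probe sets (0.120) and no trend of variance (0.111).

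Circadian clock genes were shifted downward, with 14 of 18 lower and a median log2 fold change of −0.14 (camera adjusted p = 0.0209, and adjusted p = 0.427 with an estimated correlation). Per3 and Cry2, both repressors of the clock, passed adjusted over the list alone, Cry2 at 932 ± 218 in control and 499 ± 112 in garlic livers. Rora, a nuclear receptor of the clock, was at 2109 ± 136 and 1712 ± 36.6. Per1 went the other way, at 342 ± 57.3 and 467 ± 121 (log2 fold change 0.42). The call was lost without control replicate 3 (adjusted p = 0.153), garlic replicate 1 (0.0525) or garlic replicate 2 (0.0999), and with the mean of all probe sets (0.165). The mean shifts of the diets' arrays overlapped in 5 of the called lists, those of fatty acid synthesis, cholesterol synthesis, the proteasome, Kupffer cells and amino acid breakdown. Of the 12 lists called in all, 4 upward and 8 downward, none was called with an estimated correlation, where the smallest adjusted p was 0.427, and none with fry, where it was 0.161.

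Lists of detoxification genes, which are often studied with garlic compounds, were not called. Targets of Nrf2, the regulator of antioxidant defence, had 11 of 20 members higher, a median log2 fold change of 0.04, a mean of −0.01 and an adjusted p of 0.781. For glutathione S-transferases the median was −0.02 over 18 genes (adjusted p = 0.653). For targets of the xenobiotic receptors CAR and PXR the median was −0.01 and the mean −0.14 over 14 genes (adjusted p = 0.653). Nqo1, a quinone reductase driven by Nrf2, was at 343 ± 34.0 in control and 224 ± 68.7 in garlic livers (log2 fold change −0.61, 95% interval −1.09 to −0.13, adjusted p = 0.363). Ephx1, an epoxide hydrolase, was at 12434 ± 1935 and 16928 ± 5062 (log2 fold change 0.42, 95% interval 0.024 to 0.81, adjusted p = 0.444), and its log2 fold change was 0.18 without garlic replicate 2. The difference was 0.17 (−0.16 to 0.50) for Gclc, 0.20 (−0.11 to 0.52) for Hmox1 and −0.01 (−0.38 to 0.37) for Srxn1. Adjusted over the list alone Ces1g, a carboxylesterase, passed as lower at 5741 ± 615 and 3695 ± 717, as did Gstt3 among the glutathione S-transferases at 2460.2 ± 263 and 1641 ± 169. Gstm1 differed by 0.07 (−0.16 to 0.31) and Gstm3 by 0.01 (−0.50 to 0.52). Among cytochromes P450, Cyp3a11 differed by 0.08 (−0.06 to 0.22), Cyp1a2 by 0.01 (−0.21 to 0.23) and Cyp2e1, which metabolises ethanol and acetaminophen, by −0.10 (−0.25 to 0.06). Cyp2b10, the classical target of CAR, did not pass the signal filter, at 80.5 and 79.6, and Cyp2b9 was at 2002 ± 1015 and 746 ± 154 with an adjusted p of 0.301 (0.010 without control replicate 2).

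**Figure D3:**
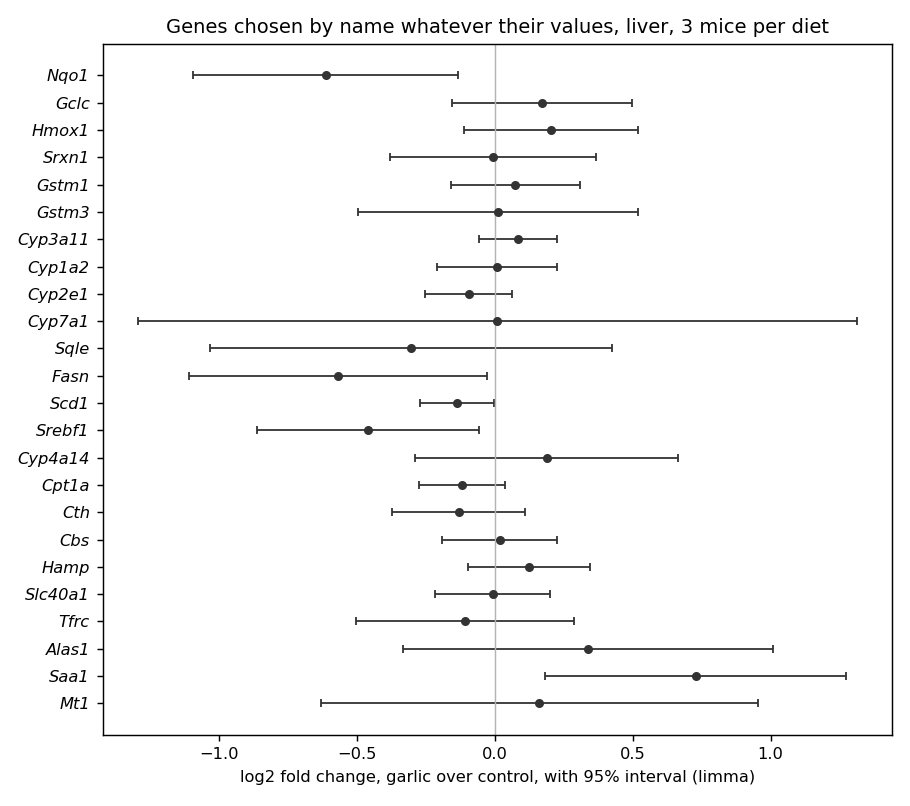
Log2 fold change, garlic over control, with its 95% interval from limma (3 mice per diet), of the 24 genes that were named whatever their values and passed the signal filter. Intervals of Nqo1, Fasn, Srebf1, Scd1 and Saa1 leave out 0 before adjustment, and none of the genes passed after it.

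Genes of lipid, iron and acute-phase biology were also named whatever their values, and none passed. Srebf1, the activator of lipogenic genes, differed by −0.46 on the log2 scale (95% interval −0.86 to −0.06), and by −0.28 without garlic replicate 2. Scd1 differed by −0.14 (−0.27 to −0.0032), with its other probe set at −0.38, and Sqle, a cholesterol synthesis enzyme, differed by −0.30 (−1.04 to 0.43). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, varied so widely between mice that its interval ran from −1.29 to 1.31. In fatty acid oxidation Cpt1a differed by −0.12 (−0.28 to 0.04) and Cyp4a14 by 0.19 (−0.29 to 0.67). In cysteine synthesis Cth differed by −0.13 (−0.37 to 0.11) and Cbs by 0.02 (−0.19 to 0.23). The iron exporter Slc40a1 differed by −0.01 (−0.22 to 0.20), the transferrin receptor Tfrc by −0.11 (−0.51 to 0.29), and Alas1, which starts heme synthesis, by 0.34 (−0.33 to 1.01). Saa1, an acute-phase protein, was at 6205 ± 1952 in control and 10348 ± 3555 in garlic livers (adjusted p = 0.340), and the metallothionein Mt1 at 7535 ± 2783 and 8734 ± 3873.

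The lists not called covered other metabolic pathways, immune responses and cell types. Over these 26 lists medians ran from −0.22 to 0.17 and adjusted p from 0.0583 to 0.903. The lowest of these p-values belonged to gluconeogenesis and glycogen, with 8 of 16 members higher. Heme metabolism had 15 of 19 members higher, a median of 0.10 and an adjusted p of 0.0702. Hepatocyte markers had a median of −0.08 over 9 genes and a mean of 0.03 (adjusted p = 0.495), and markers of stellate cells and fibroblasts a median of 0.02 over 12 genes (adjusted p = 0.653). A further 6 lists, the targets of the aryl hydrocarbon receptor and the markers of cholangiocytes, T and NK cells, erythroid cells, exocrine pancreas and muscle, had fewer than 5 members past the signal filter and were not tested.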

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

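The test of RNA degradation below was chosen only after the result was seen, and the splicing list was drawn up after some of its genes had been seen.

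The control probe set for the 3-prime end of 18S ribosomal RNA, which takes no part in the comparison of the diets, read 22213 on the array of garlic replicate 2, against 4223.5 on the highest control array, a 5.26-fold difference. The probe sets for the 5-prime end and the middle of 18S RNA read 14183 and 7255 on that array, against highest control values of 4852 and 2615. The cause was not tested.

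Heat shock protein and endoplasmic reticulum stress genes were higher in garlic livers, with a median log2 fold change of 0.32 over the 44 genes of both lists. Dependence of this median on a single array is argued against. The lowest median with any 1 array left out was 0.25 (without garlic replicate 3), above 0.5 times the median over all arrays. Its 95% bootstrap interval of 0.22 to 0.38 is over genes and does not measure the spread between mice. In garlic replicates 1, 2 and 3 the mean shift was 0.32, 1.07 and 0.81 for heat shock proteins (controls −0.03 to 0.05). For endoplasmic reticulum stress it was 0.22, 0.28 and 0.41 (controls −0.11 to 0.13). The choice of probe set or cross-hybridization cannot be told apart from a change of the transcripts: over 30 genes with further probe sets, those had a median of 0.18 (95% interval 0.065 to 0.41) against 0.29 for the brightest ones, and the interval reaches below 0.5 times that shift. An effect of the garlic diet stays open as a hypothesis, as does any difference in the handling of the mice, which the labels do not describe.

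Splicing factor and nuclear RNA genes had lower signals in garlic livers: 41 of 53 members of the list lay below 0, and 34 of the 46 that had not been seen before, with a median log2 fold change of −0.11 for the latter. Over these 46 genes, of which 11 were lower and 1 higher at an unadjusted p under 0.05, camera gave p = 0.000473 with the preset correlation and p = 0.108 with an estimated correlation, so the shift of the list is not called with the latter. A candidate explanation is a lower share of unspliced or nuclear RNA in the garlic samples. Probe sets with no gene name differed from named ones of the same signal by −0.13 on the log2 scale. All 3 garlic arrays (−0.13, −0.08 and −0.0035) lay below all 3 control arrays (0.11, 0.05 and 0.04). No genome was used, so it is not known whether these probe sets measure unspliced or nuclear RNA. The highest value, 0.11, was that of control replicate 1, the array with the brighter background. RNA degradation cannot be told apart, because the log2 ratio of the 3-prime to the 5-prime signal of Actb differed by −0.066 with a 95% interval of −0.32 to 0.19, wider than the shift of the list, although that of Gapdh differed by only 0.016 (−0.021 to 0.053) and the garlic ratios of Actb (1.44, 1.67 and 1.36) lay on both sides of the control ones (1.51 to 1.63). The brighter background of control replicate 1 cannot be told apart either, since the median of the unseen members without it was −0.071 with a 95% interval of −0.18 to −4.7e-05, and an effect of the diet stays open.

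Clock genes were lower in garlic livers. A difference in the time of collection, which the labels do not give, cannot be told apart from an effect of the diet. The arm of Arntl and the arm of Dbp and the Per genes peak at opposite times of day. The gap between the arms was taken on each array, from 13 genes in all. It differed between the diets by 0.061 on the log2 scale. The 95% interval of −0.74 to 0.86 comes from the spread between arrays, not between genes, and is too wide to decide.

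The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. With the real split 1197 genes had an unadjusted p under 0.05, and the highest other split gave 856, so 1 split, the real one, gave a count as large. For gene lists 3 splits, the real one included, gave at least the real 12. The other splits gave 10, 9, 10, 10, 13, 7, 5, 3 and 13 lists. The number of lists called with the preset correlation therefore does not set the diets apart from other groupings of the arrays. Only the number of lists was counted, so the splits do not grade the adjusted p of any single list. For genes past the adjusted threshold in limma all 10 splits gave at least the real count of 0, and the highest other gave 1.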

How the results depend on the processing

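No alternative was added after the results were seen. For the 86 named genes that were tested, 1570 of 1633 values under the alternatives kept their direction and their side of the threshold, 26 passed it and 37 changed sign, the latter in 12 genes that had been named whatever their values and lay close to 0. None of the 86 genes passed in the main fit, and many were chosen for a small p or for groups that do not overlap. A high share of unchanged values was therefore partly set by that choice. The lists of heat shock proteins, endoplasmic reticulum stress, fatty acid synthesis and MHC class II kept their calls under every alternative except an estimated correlation and fry, which ended the calls of all 12 lists and left 0. Robust variances and treat give no test of lists. Without garlic replicate 2 the number of lists called was 7, and over the arrays left out in turn it ran from 7 to 13. Over the same arrays the number of genes past the adjusted threshold ran from 0 to 6 for higher and from 0 to 4 for lower. Leaving out garlic replicate 2 or control replicate 1 gave 0 and 0. The cause was not tested. The counts at an unadjusted p under 0.05 (genes higher 530, genes lower 667) were 889 and 1620 with every probe set on its own, where more units are tested, and 85 and 177 with treat, where the null is wider. Over the arrays left out in turn they ran from 353 to 621 and from 496 to 751. Signals near background limit dim genes, and 3 arrays per diet limit all values.

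Taking the replicate number as a block gave 12 genes higher and 8 lower in garlic livers, against 0 and 0 in limma without it (530 and 667 at an unadjusted p under 0.05), and 14 lists. The smallest adjusted p in limma with the block was 0.0063. Of the genes with the smallest p named in the results, Hspa1b, Manf, Dynll1 and Tsc22d3 passed as higher. Pnn, Gckr, Srsf5 and Mir22hg passed as lower. The labels do not pair the mice. As a check, the mean of the diet group was subtracted from each gene, and the deviations were correlated between arrays across the diets. For arrays that share a number these correlations of deviations were 0.038, 0.052 and 0.084, the 3 highest of the 9 pairs. The other 6 ran from −0.070 to 0.017. All 9 are under 0.1, so the blocked counts are given as an alternative and not as the result. Whether mice of a number were handled together is left open. The cause was not tested.

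Besides those given in the report and those that changed sign, the following log2 fold changes of named genes moved by over 1.5 times. With the mean of all probe sets Hsp90aa1 was 0.23, C1qb 0.29, Rora −0.16, Pfkfb3 0.73, Gclc 0.11 and Scd1 −0.26, with quantile normalization Scd1 was −0.086 and Cyp2e1 −0.0038, and with array weights Alas1 was 0.18. Without garlic replicate 3 Saa1 was 0.47, Lpin1 0.52 and H2-Eb1 −0.38, without garlic replicate 1 Idi1 was −0.77, and without control replicate 1 Hmgcs1 was −0.27. With each array left out in turn Alas1 ran from 0.041 to 0.70, Sqle from −0.75 to −0.041, Gclc from 0.023 to 0.31, Hmox1 from 0.086 to 0.27 and Cyp2e1 from −0.14 to −0.024, the lowest size being without garlic replicate 2 for all but Hmox1, where it was without garlic replicate 1.

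Some log2 fold changes close to 0 changed sign. With quantile normalization Srxn1 was 0.016, Gstm3 −0.0041, Cyp1a2 −0.030, Cyp7a1 −0.0028 and Cbs −0.022. With arrays centred on the median Srxn1 was 0.010 and Slc40a1 0.0090. With the mean of all probe sets of a gene Cbs was −0.050, Slc40a1 0.0010 and Mt1 −0.057, and with array weights Cyp1a2 was −0.025 and Cyp7a1 −0.26. With each array left out in turn the values ran from −0.15 to 0.14 for Srxn1, −0.032 to 0.18 for Gstm1, −0.29 to 0.21 for Gstm3, −0.079 to 0.10 for Cyp1a2, −0.40 to 0.76 for Cyp7a1, −0.078 to 0.36 for Cyp4a14, −0.20 to 0.0035 for Cth, −0.049 to 0.079 for Cbs, −0.0086 to 0.21 for Hamp, −0.074 to 0.081 for Slc40a1, −0.24 to 0.12 for Tfrc and −0.16 to 0.61 for Mt1. The cause was not tested.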

Other observations

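All tests in this part are those of lists fixed in advance, except that of glucocorticoid-induced genes, whose list was drawn up after some genes had been seen.

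Single members of lists that were not called passed when adjusted over the list alone, without passing over all genes. Such passes are not adjusted for the number of lists. Gluconeogenesis and glycogen had a median log2 fold change of 0.04 and a mean of 0.24 over 16 genes (adjusted p = 0.0583). Pfkfb3, which makes the activator of glycolysis fructose 2,6-bisphosphate, was at 248 ± 87.7 in control and 551 ± 151 in garlic livers. Igfbp1, a secreted binder of insulin-like growth factors that fasting induces, was at 2307 ± 1547 and 4323 ± 582. The groups overlapped in Igfbp1, with control replicate 3 at 4087 and garlic replicate 2 at 3757. In bile acid metabolism (adjusted p = 0.479) Cyp7b1, an enzyme of the alternative pathway of synthesis, was at 14726 ± 3685 and 22134 ± 2168, and Nr0b2, the repressor SHP, at 1720.2 ± 388 and 2912 ± 715. Irf7, an interferon regulatory factor, was at 1404 ± 71.1 and 1923 ± 125 in a list of interferon-induced genes with a median of −0.056 and a test pointing upward (adjusted p = 0.903). The sulfotransferase Sult5a1 was at 486 ± 73.5 and 787 ± 98.1 (list adjusted p = 0.599), and the water channel Aqp8 at 5308 ± 1283 and 2716 ± 876 (list adjusted p = 0.838).

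Adjusted p of the other lists that were not called was 0.140 for ribosomal proteins, 0.277 for apolipoproteins, 0.284 for oxidative phosphorylation, 0.653 for neutrophil markers, acute-phase proteins, iron metabolism, targets of PPAR alpha and sex-biased genes, 0.683 for the cell cycle, 0.687 for zonation, 0.781 for complement and coagulation and for other cytochromes P450, 0.836 for antioxidant enzymes and 0.838 for globins. With the mixed test of fry, which asks whether genes of a list differ in either direction, 4 lists passed: complement and coagulation (adjusted p = 0.00108), the circadian clock (0.00504), endothelium (0.0294) and the urea cycle and amino acid breakdown (0.0433).

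Tsc22d3 and Tat, both induced by glucocorticoids, had higher signals in garlic livers, which raised the hypothesis that the garlic mice may have had a higher glucocorticoid signal. Over 19 glucocorticoid-induced genes not looked at before, 9 lay above 0 and the median log2 fold change was −0.021 (95% bootstrap interval −0.20 to 0.27). At an unadjusted p under 0.05 in limma, 4 were higher and 3 were lower, the latter including Fkbp5. Camera gave p = 0.817 with the preset correlation and 0.814 with an estimated one, so no upward shift of these genes was seen. Because the members go both ways and the interval reaches 0.27, the hypothesis stays undecided.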
